A study of Mus musculus with 8 samples.

How the data were processed

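RNA was isolated from the whole shaved back skin of 8-week-old mice labelled as Flg knockout (4 libraries) or wild type (4 libraries). Filaggrin is made in the uppermost living layers of the epidermis from the large precursor profilaggrin, the product of Flg. Per the labels, RNA came from a Qiagen column kit and was sequenced on an Illumina NextSeq. The labels name 2 library protocols: the series' design text gives a SMART protocol, and the sample labels give a strand-specific Ultra II Directional kit. Which of them was used was not settled here, so neither was assumed in any test. Per the submitters' processing notes, reads were aligned with GSNAP to the mouse build mm10 and counted per gene with featureCounts 1.6.2. The strand setting and the handling of reads with several alignments are not given in the sources used here. Reads of overlapping or antisense genes and of related family members (the repeats of Flg, Flg2 and Hrnr, and the Serpina1, Stfa and Ear families) therefore carry an uncertainty of assignment.

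The deposited values are raw read counts per gene, whole numbers with no normalization, in a table of 49763 features. Of these, 92 were spike-in sequences with at most 3 reads in any library, which were left out, and 49671 were genes. A symbol was found for 49326 gene identifiers in the GENCODE annotation of the same build, and 45128 genes had the same start and end there. Library totals were 34263154, 24495725, 23817186 and 25725124 counts for wild-type replicates 1 to 4. They were 38545957, 18483242, 24686151 and 26723517 for knockout replicates 1 to 4. Replicates were numbered in the order of the samples, so a number pairs nothing. The labels do not say outright that each library came from a separate mouse, and p-values then measure the spread between these samples. No replicate pair agreed within counting noise: chi-square per degree of freedom was 5.8 or more in every pair. Knockout replicates 2 and 4 were the closest at 5.8, and knockout replicates 2 and 3 the next closest at 16.92. Leaving out replicate 2 or 4 of knockout left the fewest called genes, as given below. Whether replicates 2 and 4 were separate mice was not tested. CPM values, counts scaled to the size of each library, were computed from these deposited counts.

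The comparison of knockout with wild type used edgeR 4.0.16 (R 4.3.3) on all 8 libraries with genotype as the only term. Genes were kept with filterByExpr, which left 19099, library composition was scaled with TMM factors, and the robust quasi-likelihood test gave p-values that were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. Log2 fold changes are knockout over wild type, and standard errors (SE) were derived from the F statistic. Mean and SD of CPM are over the 4 libraries of a group. Flg was also tested with a two-sided exact permutation test over the 70 assignments of the 8 libraries, in which 0.0286 is the smallest p that can be reached. The common biological coefficient of variation was 15.9%.

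Before the data were examined, 39 gene lists were written from textbook knowledge of skin: barrier and keratinocyte genes, inflammatory pathways, markers of the cell types and appendages of back skin, and signs of sample quality. Of their 932 entries, 2 matched no gene name. The 38 lists with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated for each list. The genes named in the text were fixed by a rule in advance: Flg, the 10 largest called changes in each direction among named genes with a mean log2 CPM of at least 1 and no overlap between genotypes, up to 4 members of each described list with the smallest p, and the genes of the fused S100 family beside Flg. Genes outside the rule are said to be chosen after their values were seen. A gene that the rule names is not reported here. Genes whose start lay within 10 Mb of Flg were compared with all other genes by a one-sided Fisher's exact test.

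The fit was tested on simulated data with the real means, dispersions and library sizes of the 19099 genes, 200 of them changed. It recovered 52.2% of genes changed 1.5-fold, 71.6% of genes changed 2-fold and 95.5% of genes changed 4-fold, with 5.2% false calls. With no gene changed it called 0 genes and passed 0 lists. The simulated genes vary independently, unlike real ones. The alternatives were other scaling factors, DESeq2 1.42.0, limma voom with quality weights per library, other filters, equal depth and each library left out in turn. Marker lists or 1 surrogate variable (sva 3.50.0) as a covariate, and other set tests, were also used. Covariates of adipocyte genes and offsets for gene length and GC content were added after seeing the data, with a GC value for 99.7% of tested genes. A sex covariate was planned and could not be fitted, because Xist was at 864 CPM or more in every library and no Y-linked gene examined exceeded 0.367 CPM. Figures were drawn with matplotlib.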

Results

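The data were read counts of whole back skin from 4 wild-type and 4 Flg knockout samples, with library totals between 18483242 and 38545957 counts. The series was set up to ask how Flg deficiency alters gene expression in the skin as a whole. Because the tissue was not separated, every value averages epidermis, hair follicles, glands, dermis, muscle and fat.

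Flg (ENSMUSG00000102439, chromosome 3, positions 93273523 to 93293686 on the plus strand, mm10) was lower in every knockout library than in every wild-type library. Its level was 59.0 ± 9.77 CPM (SD, n = 4) in wild type and 24.5 ± 1.97 CPM (SD, n = 4) in knockout, which is 41.6% of wild type. The log2 fold change was -1.27 ± 0.12 (SE), with an edgeR adjusted p of 0.00326. The exact permutation p was 0.0286, the smallest that 4 against 4 libraries allow. Raw Flg counts were 2317, 1175, 1331 and 1682 in wild type and 1027, 461, 579 and 595 in knockout. The neighbouring fused S100 genes, which encode related proteins of the cornified layer and hair, did not pass the edgeR test. Flg2 had a log2 fold change of 0.02 ± 0.10 (SE, adjusted p = 0.926), Hrnr of 0.19 ± 0.08 (adjusted p = 0.206), Rptn of -0.72 ± 0.47 (adjusted p = 0.432) and Tchh of 0.36 ± 0.41 (adjusted p = 0.655).

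**Figure D1:**
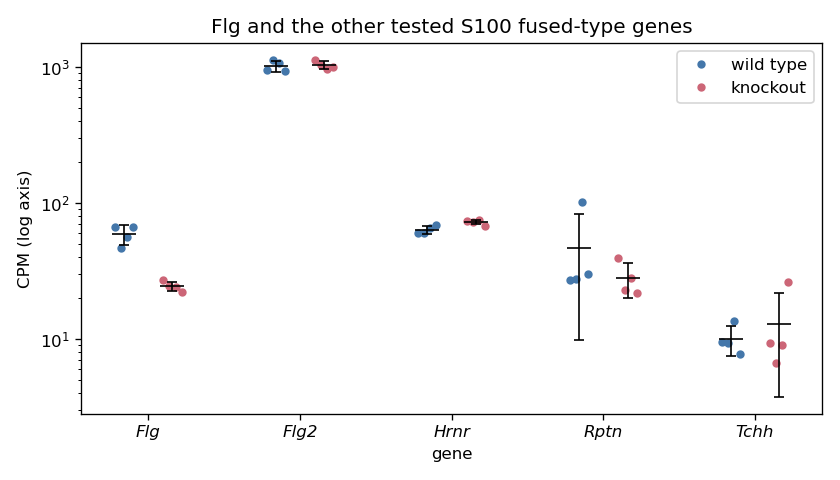
CPM on a log axis for Flg and 4 other genes of its family, with 1 point per library, wild type in blue and knockout in red, and bars for the mean and SD of 4 libraries. Flg lies between 22.3 and 27.0 CPM in knockout and between 46.4 and 66.9 CPM in wild type, and the genotypes overlap for the other 4 genes.

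Across the skin transcriptome, the adhesion molecule gene Dscam was among the genes that rose most in knockout, at a log2 fold change of 2.21 ± 0.30 (SE, n = 4 per group). The oxytocin receptor gene Oxtr (chromosome 6, positions 112473683 to 112489943) rose from 24.1 ± 4.16 to 91.6 ± 16 CPM. The thyrotropin receptor gene Tshr rose by 2.10 and Mrap, which encodes a partner of melanocortin receptors, by 1.70 on the log2 scale. Both were highest of wild type in wild-type replicate 3 and lowest of knockout in knockout replicate 3. The mean of the white adipocyte list, given below, had the same extremes. Oxtr shared the knockout extreme but was lowest of wild type in wild-type replicate 3. These orders were compared after the values were seen, and whether fat amount accounts for the increases is left open. Lctl, Rgs7, Serpina1b, Bmp8a and Rasd1 rose by between 1.73 and 2.12. The largest decrease among called genes with a mean log2 CPM of at least 1 was in the matrix metalloproteinase gene Mmp11 (chromosome 10, positions 75923222 to 75932502). It fell from 73.1 ± 36.4 to 7.51 ± 0.469 CPM, a log2 fold change of -3.28 ± 0.42 (SE). Cthrc1, which encodes a secreted protein of remodelling matrix, changed by -1.94, the pigment cell gene Mlana by -1.83, the slow muscle troponin gene Tnnt1 by -1.52 and the cartilage collagen gene Col9a3 by -1.29. Mlana was 1 of 12 members of the melanocyte list to pass over all genes, with 2 lower adjusted over the list alone. That list had 6 members above and 6 below 0 and did not pass (camera adjusted p = 0.367). Pinlyp, Myo16, Slc6a7 and Zim1 had log2 fold changes of -2.14, -1.92, -1.83 and -1.22. Of 19099 genes tested with edgeR, 270 were called, 136 higher and 134 lower in knockout. At least 2-fold changes were seen in 49 of the higher and 39 of the lower ones. At an unadjusted p under 0.05 there were 3724 genes, where 955 would be given by independent unchanged genes. Other splits of the 8 libraries into 4 and 4 gave between 108 and 2995 such genes, and 2334 in a split with 2 libraries of each genotype on either side. No overlap of CPM between genotypes was seen in 2200 genes (11.5%, against 2.86% by chance). The counts changed when single libraries were left out. They were 679 higher and 646 lower without wild-type replicate 3, and 188 and 316 without wild-type replicate 2. They were 37 and 26 without wild-type replicate 1, and 37 and 25 without wild-type replicate 4. Without knockout replicates 1, 2, 3 and 4 they were 51 and 26, 9 and 2, 73 and 56, and 11 and 4. With the mean of the white adipocyte list as a covariate, added after seeing the data, they were 1 and 1. With limma voom with quality weights they were 1193 and 1363.

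Among barrier genes, the precursors of the cornified envelope encoded beside Flg did not pass the test as a group. Of 29 tested members 0 passed over all genes and 0 adjusted over the list alone (camera adjusted p = 0.799). Sprr1a had a log2 fold change of -0.64 ± 0.25 and Lce1l of 0.33 ± 0.18 (SE), neither past the test. Genes of profilaggrin processing and natural moisturizing factor gave 0 of 15 over all genes and 0 adjusted over the list alone (camera adjusted p = 0.677). Casp14 stood at -0.17 ± 0.09 and Ggct at -0.21 ± 0.09. Barrier lipid synthesis and transport gave 0 of 32 over all genes and 0 adjusted over the list alone (camera adjusted p = 0.649). In contrast, suprabasal keratinocyte genes were lower by camera (adjusted p = 0.0451; adjusted p = 0.462 with an estimated correlation), with 4 of 31 members lower over all genes and 5 adjusted over the list alone. Cst6, which encodes the protease inhibitor cystatin E/M, fell from 454 ± 104 to 250 ± 21.7 CPM. The other 3 were the transglutaminase gene Tgm5 at -0.57 ± 0.08, Lypd3 at -0.48 ± 0.09 and Calml3 at -0.40 ± 0.08. Desquamation proteases and inhibitors were lower by camera (adjusted p = 0.00502; adjusted p = 0.462 with an estimated correlation), with Cst6, which both lists hold, passing among 20 members and 3 lower adjusted over the list alone. Klk7 at -0.38 ± 0.09 did not pass over all genes. In the list of tight junction, hydration and pH genes (camera adjusted p = 0.0551), the water and glycerol channel gene Aqp3 fell from 96.4 ± 9.02 to 61.7 ± 2.17 CPM. It was 1 of 15 members over all genes and 4 adjusted over the list alone. Without wild-type replicate 3 the calls of the suprabasal and desquamation lists ended (camera adjusted p = 0.343 and 0.126), as did the suprabasal call without knockout replicate 1 (0.0799) or 3 (0.0839). The suprabasal call also ended with length and GC offsets. The tight junction list passed without wild-type replicate 1 (0.0226) or 4 (0.0404) and without knockout replicate 1 (0.0428) or 2 (0.0411). With the adipocyte list mean as a covariate, added after seeing the data, it passed as lower as well (0.00089). So did the cornified envelope (0.00932), profilaggrin processing (0.009) and barrier lipid (0.0034) lists. Basal keratinocyte genes gave 0 of 14 over all genes and 0 adjusted over the list alone (camera adjusted p = 0.649). Cell cycle genes gave 0 of 34 and 0 (camera adjusted p = 0.507, and 0.00322 without knockout replicate 3).

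T cell lists were lower by camera in knockout skin, though not with an estimated correlation. The list of dendritic epidermal T cell genes, resident gamma-delta T cells of mouse epidermis, had a median log2 fold change of -0.77 and 13 of 14 members below 0 (camera adjusted p = 1.27e-05; adjusted p = 0.31 with an estimated correlation). None of its members passed over all genes (0 of 14, with 9 lower adjusted over the list alone). The granzyme gene Gzmc stood at -2.06 ± 0.41 (SE, adjusted p = 0.0514). T cell and natural killer cell genes were lower by camera (adjusted p = 1.27e-05; adjusted p = 0.462 with an estimated correlation), with 2 of 25 lower over all genes and 11 adjusted over the list alone. Those 2 were Cd2, an adhesion receptor of T cells, at -0.82 ± 0.17 and Ncr1, a natural killer cell receptor, at -1.13 ± 0.24. Cd163l1, a scavenger receptor of gamma-delta T cells, fell from 10.4 ± 2.01 to 4.76 ± 0.471 CPM. It was the member of the interleukin 17 list to pass (1 of 13 over all genes; 1 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.34). B cell and plasma cell genes gave 0 of 10 over all genes and 5 lower adjusted over the list alone (camera adjusted p = 0.0764). That list passed without wild-type replicate 2 (0.0115) and without knockout replicate 2 (0.0411) or 3 (0.0444).

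Of the 6 inflammatory lists none passed camera in the main comparison. With the adipocyte list mean as a covariate, added after seeing the data, the interferon list passed as higher (camera adjusted p = 0.000127). The type 2 cytokine axis (camera adjusted p = 0.168) had 1 member higher and 3 lower of 27 over all genes, and 1 higher and 5 lower adjusted over the list alone. The list passed as lower without wild-type replicate 2 (0.0257) and without knockout replicate 2 (0.0376) or 3 (0.0213). Il31ra, a subunit of the receptor for the itch cytokine interleukin 31, rose from 62.8 ± 21.4 to 130 ± 13.1 CPM. The epithelial cytokine gene Tslp fell from 9.14 ± 3.18 to 4.04 ± 0.814 CPM, the matrix gene Postn changed by -0.76 ± 0.11 and the eosinophil-associated ribonuclease gene Ear2 by -0.75 ± 0.13. In the interferon response list (camera adjusted p = 0.507) the chemokine gene Cxcl9 fell by 0.99 on the log2 scale. It was 1 of 40 over all genes, with 2 higher and 3 lower adjusted over the list alone. Keratinocyte stress and alarm genes had 1 of 26 lower over all genes, Stfa3 at -1.35 ± 0.28, and 6 adjusted over the list alone (camera adjusted p = 0.171). Oxidative stress and xenobiotic genes had 1 of 20 lower over all genes, Cyp1b1 at -0.78 ± 0.15, with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.32). Class II antigen presentation genes gave 0 of 11 and 0 adjusted over the list alone (camera adjusted p = 0.313). The interferon list passed as higher without wild-type replicate 2 (0.0115). Class II genes passed as lower without wild-type replicate 1 (0.0277), and stress genes as lower without knockout replicate 2 (0.0152). In the macrophage list (camera adjusted p = 0.251, and 0.0311 without knockout replicate 4) the mannose receptor gene Mrc1 rose by 0.58. It was 1 of 22 over all genes and 2 adjusted over the list alone. In the Langerhans and dendritic cell list (camera adjusted p = 0.562) the lectin gene Mgl2 rose by 0.78 and Epcam changed by -0.35. They were 2 of 18 over all genes, with 2 higher and 2 lower adjusted over the list alone.

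The list of white adipocyte genes was higher by camera in knockout, with a median log2 fold change of 0.71 and 19 of 21 members above 0 (camera adjusted p = 2.37e-08; adjusted p = 0.462 with an estimated correlation). It had 1 member higher over all genes and 9 adjusted over the list alone. The growth hormone receptor gene Ghr rose from 203 ± 10.6 to 400 ± 46.4 CPM, while Cfd stood at 1.18 ± 0.25 (SE, adjusted p = 0.0537). The list mean was 7.55 log2 CPM in wild-type replicate 3, against 6.75, 6.37 and 6.54 in the other wild-type libraries and between 7.19 and 7.80 in knockout. The sebaceous gland list passed camera as higher (adjusted p = 0.0232; adjusted p = 0.786 with an estimated correlation), but with 13 members above and 9 below 0, and its mean of 6.55 log2 CPM in wild-type replicate 3 exceeded all knockout libraries, at 6.17 to 6.50 (exact permutation p = 0.143 for n = 4 per group). It had 3 of 22 members higher over all genes, and 7 higher and 2 lower adjusted over the list alone. All 3 encode enzymes of fatty acid synthesis, which fat also expresses: Acaca at 1.34 ± 0.19, Acly at 0.58 ± 0.10 and Scd1 at 1.36 ± 0.24. Smooth muscle and pericyte genes were higher by camera (adjusted p = 0.0268; adjusted p = 0.462 with an estimated correlation), with 0 of 13 over all genes and 4 adjusted over the list alone. Acta2 stood at 0.48 ± 0.11. Hair follicle stem cell and bulge genes were lower (camera adjusted p = 0.0102; adjusted p = 0.462 with an estimated correlation). Postn, which the type 2 and fibroblast lists also hold, passed among 12 members, with 1 higher and 6 lower adjusted over the list alone. Calls ended for the sebaceous list without wild-type replicate 1 (0.0559) or 2 (0.171) or knockout replicate 1 (0.0545). They ended for the smooth muscle list without wild-type replicate 4 (0.0528) or knockout replicate 1 (0.0606), and for the bulge list without wild-type replicate 3 (0.0804). Length and GC offsets also ended the smooth muscle call. With the adipocyte list mean as a covariate, added after seeing the data, the sebaceous and smooth muscle calls ended as well (0.61 and 0.514). Hair shaft genes gave 0 of 20 (camera adjusted p = 0.677), and skeletal muscle genes 0 of 36 (camera adjusted p = 0.245, and 0.0179 without wild-type replicate 4). Endothelial genes gave 0 of 19 (camera adjusted p = 0.32, and 0.00318 without wild-type replicate 2) and fibroblast and matrix genes 1 of 28, Postn (camera adjusted p = 0.57). Adjusted over the list alone these were 0, 0, 2 lower, and 2 higher and 1 lower.

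**Figure D2:**
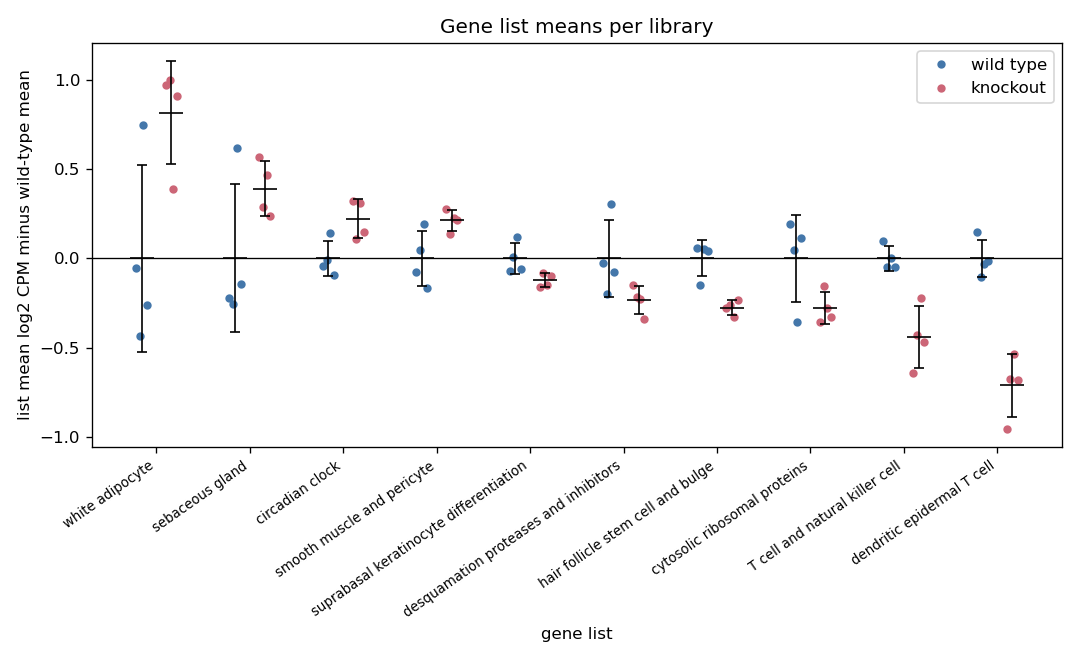
Mean log2 CPM of the members of the 10 lists that passed camera, given per library as the difference from the wild-type mean, with wild type in blue, knockout in red and bars for the mean and SD of 4 libraries. For the white adipocyte list, wild-type replicate 3 lies among the knockout libraries, and for the dendritic epidermal T cell list all 4 knockout libraries lie below all 4 wild-type libraries.

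Among signs of sample state, circadian clock genes were higher by camera (adjusted p = 0.00569; adjusted p = 0.462 with an estimated correlation). Per1 at 0.83 ± 0.12 and Bhlhe40 at 0.44 ± 0.09 were the 2 of 18 members to pass over all genes, with 3 higher and 1 lower adjusted over the list alone. With the adipocyte covariate the clock call ended (0.0799). Cytosolic ribosomal protein genes were lower (camera adjusted p = 2.34e-09; adjusted p = 0.589 with an estimated correlation). All 60 members lay below 0, with a median of -0.29 and 0 passing over all genes or adjusted over the list alone. Their list mean was 4.84 log2 CPM in wild-type replicate 3, against 5.39, 5.24 and 5.31 in the other wild-type libraries. In knockout it was between 4.84 and 5.04 (exact permutation p = 0.114 for n = 4 per group). The ribosomal call ended with the adipocyte covariate (0.667). Across genes, which are not independent replicates, log2 fold change was correlated with exon length (Spearman's rho = 0.225). With length and GC offsets the ribosomal list, whose transcripts are short, had a median of -0.21 on log2 CPM against -0.27 without them, and still passed camera (adjusted p = 1.72e-07). Mitochondrially encoded genes gave 0 of 15 and 0 adjusted over the list alone (camera adjusted p = 0.799). No list passed camera with an estimated correlation, where the smallest adjusted p was 0.31. Other partings of the 8 libraries into 4 and 4 passed up to 20 lists with the preset correlation. Of all 35 partings, the one by genotype included, 26 passed at least the 10 seen between genotypes. The first principal component held 34.9% of the variance and placed wild-type replicates 1 and 4 at -43.9 and -38.7, apart from replicates 2 and 3 at -3.0 and 1.3 and from the knockout libraries at 10.8 to 26.9.

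Genes near Flg were called no more often than others. Of 361 tested genes that start within 10 Mb of it, 4 were called (Thbs3, S100a14, Cd2 and Tspan2, named after their values were seen), against 265 of 18737 elsewhere, an odds ratio of 0.78 (one-sided Fisher's exact p = 0.751).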

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

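The tests of Flg reads, of tissue amounts and of length and GC content below were chosen after the results they concern had been seen, and the regrouping of libraries was planned.

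The number of called genes was set against every other way to part the 8 libraries into 4 and 4. Of 35 splits, 1 gave as many as 270 calls, the real one, and the highest other split gave 1 call. Chance is thereby argued against for this count, though 1 in 35 is the strongest result that this test can give. The number of lists that passed camera did not stand out: 26 of the 35 splits, the real one included, passed as many as the real 10, and the highest other split passed 20. Chance is therefore not excluded for the list calls taken as a number.

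Flg transcript remained at 41.6% of wild type in knockout. A knockout library that is in fact wild type is argued against, since 0 knockout libraries reached the lowest wild-type value. Reads of the repeat-rich relatives Flg2 and Hrnr counted for Flg could account for the remainder and cannot be told apart from residual Flg transcript with counts per gene: the knockout level of Flg is 2.2% of their summed level. The kind of targeted allele, which may leave part of the transcript, is not given in the labels and was not tested.

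White adipocyte genes were higher in knockout. Length or GC content bias is argued against, since the list median on log2 CPM was 0.79 before and 0.82 after offsets for both. More fat in the knockout pieces cannot be told apart from a change within fat. Of 21 list members 8 departed from the common change, 4 above it (with Lep at 2.43) and 4 below it (with Fabp4 at -0.10 and Aqp7 at -0.49; these 3 genes were chosen after their values were seen), but centring forces departures on both sides, other cells express some members, and no member fell by the test. An effect of genotype on fat stays open and untested.

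Dendritic epidermal T cell genes were lower in knockout. Less epidermis, or dilution by other tissue, is argued against as the source of the whole fall, but a smaller loss of epidermis is not excluded. Basal keratinocyte genes had a list mean of 8.29 ± 0.05 log2 CPM in wild type and 8.25 ± 0.09 in knockout (SD, n = 4). Of its members 10 lay below 0 and 4 above, none past the edgeR test. Among them Krt15 stood at -0.41 ± 0.14, Krt14 at -0.25 ± 0.12, Krt5 at -0.21 ± 0.11 and Dst at 0.36 ± 0.17 (SE). Relative to them in the same library the dendritic epidermal T cell list fell by 0.67 on the log2 scale (exact permutation p = 0.0286, lower in 4 of 4 knockout libraries). That list had the same exact permutation p before basal genes were subtracted, so the p is no separate evidence. Length or GC content bias is argued against too, with a list median of -0.68 before and -0.62 after the offsets. A lower number of these cells, or a lower expression in each, in knockout skin remains a hypothesis, found and tested on the same libraries. The T cell and natural killer cell list was lower by camera too, with the natural killer cell receptor gene Ncr1 called at -1.13 ± 0.24 (SE). Whether the fall is particular to dendritic epidermal T cells was not tested.

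Single libraries lay far from the other 3 of their group in 31 of 416 groups examined, where chance gives about 20.8. The list means, in log2 CPM, were 8.37 for basal keratinocyte genes, 6.55 for sebaceous gland genes and 2.38 for neutrophil genes in wild-type replicate 3, 6.51 for hair follicle stem cell genes in wild-type replicate 2 and 6.15 for macrophage genes in wild-type replicate 4. In knockout they were 2.33 for interleukin 17 genes, 3.32 for melanocyte genes and 2.72 for erythroid genes in replicate 1, and 7.19 for white adipocyte genes and 2.16 for neutrophil genes in replicate 3. Single genes of wild-type replicate 2 stood apart at 3.20 (Zim1), 6.57 (Il31ra), 6.02 (Cyp1b1), 4.15 (Mcm3), 5.84 (Krt75), 5.65 (Lhx2), 2.60 (Ctsw) and 0.86 (S100a9) log2 CPM. Those of wild-type replicate 3 were at 6.68 (Rptn), 6.76 (Txnrd1), 5.81 (Acaca), 5.19 (Pparg) and 2.57 (Tcrg-C1), and Cacna1s was at 6.70 in wild-type replicate 1. In knockout, replicate 1 stood apart for Tcrg-C1 (1.11), Alox15 (2.46) and Ccn1 (6.35), replicate 2 for Myo16 (-0.71) and Ggct (5.96), replicate 3 for Plin4 (8.37) and replicate 4 for Batf3 (0.90).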

How the results depend on the processing

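The covariate of adipocyte genes and the offsets for length and GC content were chosen after seeing the data. No paired analysis was possible because the labels give no replicate numbers. The planned sex covariate was not run, since all libraries looked female. The log2 fold change of Flg lay between -1.38 and -1.16 in every alternative and between -1.36 and -1.20 with 1 library left out, and passed in all but the adipocyte covariate (-1.30, adjusted p = 0.0685). There its SE went from 0.12 to 0.18, and over the 270 called genes the median size of change went from 0.79 to 0.77 and the median SE from 0.14 to 0.19. At the median, then, the error widened while the size of change stayed about the same, and 55.7% of the covariate's variance lay between genotypes. A median does not exclude that some of the calls shrank with the covariate. Genes called higher and lower numbered 591 and 551 with DESeq2, 1193 and 1363 with limma voom with quality weights, and 234 and 268 without a filter. They numbered 526 and 388 with 1 surrogate variable, 48 and 29 with a skeletal muscle covariate, 22 and 11 against a fold of 1.2, and 1 and 1 with the adipocyte covariate. Beyond these explanations the cause was not tested. With 1 library left out they ranged from 9 to 679 higher and from 2 to 646 lower, both lowest without knockout replicate 2 and highest without wild-type replicate 3. With library size alone as the scaling they were 133 and 178, and with RLE factors 137 and 98. Of 43 called genes named by the rule, 43 were kept by DESeq2 and by limma voom with quality weights, and 37 with length and GC offsets. At equal depth 36 were kept, 18 with the muscle covariate, 10 against a fold of 1.2 and 0 with the adipocyte covariate. Without knockout replicates 2 and 4, 3 and 4 were kept, and 0 reversed in any setting. Lists passing numbered 0 higher and 0 lower with an estimated correlation, and 0 and 3 with fry, another set test. Those 3 were the dendritic epidermal T cell (fry adjusted p = 0.0186), bulge (0.0186) and T cell and natural killer cell (0.0493) lists. The white adipocyte and ribosomal lists did not pass fry (0.108 and 0.176). With the adipocyte covariate 5 and 14 lists passed camera. Of those 5 higher lists 0 were among the 4 reported: the adipocyte list was left out, and the sebaceous, smooth muscle and clock lists lost their calls (adjusted p = 0.61, 0.514 and 0.0799), as did the lower ribosomal list (0.667). The cornified envelope list turned to lower (0.00932). Lists that had not passed did so, among them profilaggrin processing (0.009), barrier lipids (0.0034) and tight junction (0.00089) as lower. Interferon response (0.000127) and mitochondrially encoded genes (9.1e-06) were among those that passed as higher. With 1 library left out they ranged from 2 to 5 higher and from 3 to 11 lower: without wild-type replicates 2 and 3, 11 and 3 were lower, without knockout replicate 2, 10 were lower, and without knockout replicate 1, 2 were higher. With length and GC offsets 3 and 5 passed, without the smooth muscle and suprabasal lists. The odds ratio near Flg was 0.52 within 5 Mb and 0.71 within 20 Mb. With every library thinned to the smallest total, 119 and 104 genes were called against 136 and 134 at full depth, and what lower or higher depth would give was not tested.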

Other observations

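All lists in this part were written, and all tests of them chosen, after the called genes had been seen.

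Of 26 tested genes of fatty acid synthesis and its supply of NADPH, 10 passed higher and 0 lower in knockout skin, 16 did not pass, and 25 of 26 lay above 0. The list was written with some of these calls in view, so their number is a description and no test. The called genes were led by the lipid droplet protein gene Pnpla3, at 1.57 ± 0.12 (SE) the call with the smallest p of all genes, and included the pentose phosphate enzyme gene G6pdx at 0.81 ± 0.12 and the carbohydrate-responsive regulator gene Mlxipl at 0.65 ± 0.14. The mean of the list went from 6.21 ± 0.30 to 6.88 ± 0.09 log2 CPM (SD, n = 4, exact permutation p = 0.0286, the smallest possible), and camera with an estimated correlation gave p = 0.0507. Both tests rest in part on the genes that prompted the list. The 16 members that were not called had a mean difference of 0.48 (exact permutation p = 0.114), with 6 at an unadjusted p under 0.05, but they are picked for weak evidence, so neither value decides whether the list moves as a group. White adipocyte genes, among them Thrsp and Dgat2 that this list also holds, were higher in the same libraries, with a median of 0.71. Of 23 genes of cholesterol synthesis and uptake, edgeR called 0, 8 had an unadjusted p under 0.05, and the mean difference was -0.09 (exact permutation p = 0.143). Whether these genes differ from those of fatty acid synthesis was not tested. Of 6 tested liver-enriched transcripts 0 passed, with 3 at an unadjusted p under 0.05.

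Rasd1, Per1 and Errfi1, which glucocorticoids induce, were called higher, and a higher glucocorticoid signal is a candidate explanation. Per1 is also a member of the circadian clock list, which was higher by camera, and these readings of Per1 cannot be told apart here. Of 19 other glucocorticoid-induced genes edgeR called 0, with 8 at an unadjusted p under 0.05 in both directions. Their mean difference was 0.29 log2 CPM, with wild type at 5.83 ± 0.45 and knockout at 6.12 ± 0.20 (SD, n = 4, exact permutation p = 0.286), so the test leaves the hypothesis open.

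The imprinted genes Peg3, Zim1, Cdkn1c and H19 were called lower, at log2 fold changes of -0.92, -1.22, -1.22 and -0.74, which makes 4 of 46 tested imprinted genes on a list that holds the 4 genes that prompted it. A lowering of imprinted genes as a group may be proposed, but the mean difference of all 46 was -0.13 (exact permutation p = 0.171) with 30 below 0, so it was not shown.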
